A study of Mus musculus with 20 samples.

How the data were processed

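RNA was sequenced from 20 primary neuron cultures of mouse embryos, per the labels: 4 controls, 8 with MeCP2 overexpression and 8 with MeCP2 knockdown. Ribosomal RNA was depleted and strand-specific single-end libraries were made, per the labels' protocols. The submitters' processing notes name Trim Galore, Bowtie, STAR and bedtools, without versions or roles, and the genome build mm9. The labels do not state whether cultures of a group came from separate litters, so p-values measure the spread between these cultures, which can be partly technical.

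One table of 64 columns and 21339 genes was used, and it holds the authors' comparisons and no values per library. It lists only genes spanning more than 3 kb (shortest 3002 bp). Its span equals stop minus start in every row, so starts can count from 0; coordinates are printed as given. In 25 rows the symbol is a number, of the kind a spreadsheet makes from a name, 6 of them called, and these were not named. Per the file headers, the RNA columns compare exonic reads of knockdown with overexpression. The log2 fold changes were deposited by the authors as knockdown over overexpression, a direction set by the column name and by Mecp2 itself. The p-value and adjusted p of each gene were deposited by the authors, and the test behind them is not given in the sources used here. The RNA p-value is present for 19906 genes and the adjusted p for 13329. The ratio of the smallest adjusted p to its p equals 14285, so the adjustment covered more genes than carry an adjusted p in the table. The TPM of wild-type cultures was computed by the authors, per the file headers, and sums to 509362 over the genes of the table. Log2 CPM columns of eTIP and ChIP were deposited by the authors beside log2 fold changes, p-values and adjusted p for promoter-associated and gene-body regions. The samples behind eTIP and ChIP are not among the labels used here, and how those regions were defined is not given in the sources used here. A further 12 columns of eTIP and ChIP levels per group, which hold infinite values, were not used. The 13329 genes with an RNA adjusted p were the tested genes; their median wild-type level was 11.1 TPM, against 0.0208 TPM for the others.

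The planned count models and fits on single libraries needed values per library and were replaced by tests on the deposited statistics. A gene was called at a deposited adjusted p under 0.05. Each p was turned into a signed normal score, and gene sets were tested against the other tested genes with camera for pre-ranked statistics in limma 3.58.1 (R 4.3.3), with a preset correlation between genes of 0.01 and again with 0.05. This test compares genes within one set of libraries and takes no account of a trend shared by a library. Benjamini-Hochberg adjustment ran over 29 gene lists, over 11 long-gene tests (1 per assay, region and comparison) and over 42 tests of brain classes and called genes. Gene lists were 30 sets fixed before the data were examined, named in the report, of which 29 had at least 5 tested members. Of 875 list entries, 802 were in the table, 4 of them under an older symbol. Long genes were those over 100 kb. Random lists matched on span and TPM were drawn 10000 times from 8 by 8 bins. Shares were compared with two-sided Fisher's exact tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

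Genes were named by a rule fixed before the data were examined: Mecp2, the 10 largest rises and 10 largest falls among called genes, up to 4 members per list with the smallest adjusted p, and the 5 longest called genes over 100 kb. Symbols of the form Gm plus digits, LOC plus digits or ending in Rik were passed over in the largest changes and longest genes. The rule asked for a mean CPM of at least 5 and for every replicate to change alike. The first was replaced by a wild-type TPM of at least 5, and the second could not be applied. The steps were tested on simulated scores for knockdown against overexpression over 13329 genes. Of 100 genes shifted by 3 standard deviations, 22% were recovered, and of 100 shifted by 6, 100%, with 5.43% false calls. Camera called 2 of 2 shifted sets of 30 genes and 2 of 50 unshifted sets. The simulated genes were independent of each other, so this does not test camera on lists whose genes move together. The recovery and false-call rates come from adjusting the simulated scores. They do not test the authors' adjusted p, from which the called genes come. The alternatives tried were other length limits, all genes with a p, comparison genes matched on TPM, for promoter eTIP in knockdown over overexpression also on promoter log2 CPM, and for gene-body eTIP on gene-body log2 CPM (1 gene per long gene, the nearest free one), ranks, a correlation of 0.05, another adjustment, a threshold of 0.1 and a TPM minimum of 1. The depth of each library is unknown, so no limits from depth were computed. Comparisons of overexpression or knockdown with control RNA were not analysed here.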

Results

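The series profiled RNA in primary neuron cultures from mouse embryos of day 14.5 in which the amount of MeCP2, a protein that binds methylated DNA and whose loss causes Rett syndrome, was raised or lowered. The labels list 20 libraries: 4 controls, 8 cultures with MeCP2 overexpression and 8 with MeCP2 knockdown. Lentivirus was added after 3 days in vitro at a multiplicity of infection of 3, and RNA was taken after 12 days in vitro. The series title names topoisomerase IIb (TOP2B), an enzyme that passes DNA strands through each other, and long neuronal genes, so transcript changes were examined by gene and by gene length. The values analysed were the authors' comparison statistics for 21339 genes, each spanning more than 3 kb, with knockdown set against overexpression for RNA. They also covered etoposide-mediated TOP2B immunoprecipitation (eTIP), an assay that uses the drug etoposide to trap TOP2B engaged on DNA, and TOP2B chromatin immunoprecipitation (ChIP). The labels give a usual yield between 15 M and 40 M reads per RNA library, and the depth of each library is unknown here. Overexpression and knockdown were not each compared with control RNA here, so every RNA direction is knockdown relative to overexpression and does not say which group moved from control. No error or n per gene accompanies these values, and the authors' adjusted p carries the spread between libraries.

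Mecp2 itself had the largest fold change of all called genes. Its transcript was 4.4-fold more abundant in overexpression than in knockdown cultures in the authors' deposited table (log2 fold change -2.14, adjusted p = 3.08e-36). The gene lies on chromosome X, 71271930 to 71331029 of mm9, and its level in wild-type cultures was 47.7 TPM. Whether reads from a viral copy are counted at this locus is not given in the sources used here. Of 13329 genes with a deposited adjusted p, 1312 passed 0.05, 555 higher and 757 lower in knockdown. Most differences were small: the median called gene differed by 0.254 on the log2 scale, a 1.19-fold difference. Only 11 called genes differed more than 2-fold, 9 of them higher and 2 lower in knockdown.

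Among genes with a wild-type TPM of at least 5, Tagln, Cnn2, Mcam, Ogn and Acta2 led the called transcripts that were higher in knockdown. Tagln, which encodes the actin-binding protein transgelin, was 1.98-fold higher in the authors' deposited table (log2 0.99, adjusted p = 0.00167). Smooth muscle actin, Acta2, was 1.64-fold higher in the same comparison of the authors' deposited table (adjusted p = 0.00139), and the calponin gene Cnn2 was 1.79-fold higher (adjusted p = 0.000578). The adhesion molecule gene Mcam and the proteoglycan gene Ogn had log2 fold changes of 0.83 and 0.80 in the authors' deposited table (adjusted p = 6.84e-07 and 0.00453). Btg2, an antiproliferative early response gene, had 0.64, and Nptx2, a synaptic pentraxin induced by activity, had 0.59 in the authors' deposited table (adjusted p = 3.79e-13 and 1.74e-10). The other 3 among the 10 largest rises at that TPM were Prss23 (0.62), Amigo2 (0.62) and Cdc42bpg (0.60), with adjusted p of 0.00161, 4.43e-06 and 1.37e-06 in the authors' deposited table.

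After Mecp2, the largest falls among genes with a TPM of at least 5 included astrocyte and cell cycle genes. Gfap, the intermediate filament gene of astrocytes on chromosome 11, 102748649 to 102762226, had a log2 fold change of -0.80 in the authors' deposited table (adjusted p = 0.00374), from a wild-type level of 66.6 TPM. The water channel gene Aqp4 had -0.78 and the cyclin gene Ccna2 -0.72 in the authors' deposited table (adjusted p = 0.00724 and 0.000193). Rxfp3, the relaxin-3 receptor gene, was 2-fold lower in knockdown in the authors' deposited table (adjusted p = 7.47e-07). Fam107a, Thrsp and Lcat had log2 fold changes of -0.91, -0.84 and -0.82 in the authors' deposited table, with adjusted p of 0.0119, 2.57e-06 and 0.00277. The growth factor gene Ptn and the caveolin gene Cav1 had -0.75 and -0.74 in the authors' deposited table (adjusted p = 0.000762 and 0.000342).

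**Figure D1:**
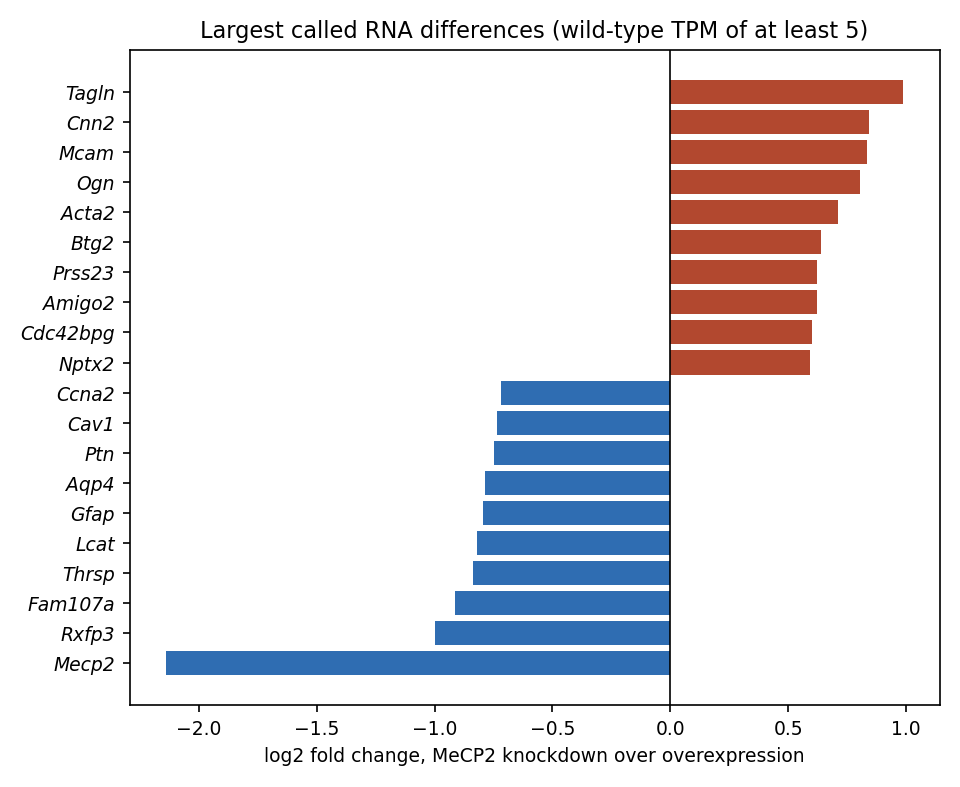
Horizontal bars give the log2 fold change (x axis) of RNA in MeCP2 knockdown over overexpression for the 10 largest called rises and 10 largest called falls with a wild-type TPM of at least 5, one gene per row, from the authors' deposited table, which gives no error bars. Mecp2 reaches -2.14, and the rest lie between -0.998 and 0.99.

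Cell division genes were lower in knockdown as a group. Of the proliferation list, 0 of 28 tested members were higher and 11 lower, or 0 and 17 adjusted over the list alone, and all 28 had a negative fold change (median log2 fold change -0.47, camera adjusted p = 8.65e-12). The mitotic genes Top2a, Cenpf and Mki67 had log2 fold changes of -0.73, -0.82 and -0.73 in the authors' deposited table (adjusted p = 3.56e-07, 7.58e-06 and 2.61e-05). The cultures were fed a DNA synthesis blocker, fluorodeoxyuridine, per the labels, and wild-type levels of these genes were low, 4.14, 2.3 and 3.48 TPM in the authors' deposited table. Astrocyte markers were lower as well: 0 of 18 tested members were higher and 3 lower, or 0 and 7 adjusted over the list alone (median log2 fold change -0.30, camera adjusted p = 0.000625). Aldh1l1, a folate enzyme gene of astrocytes, had -0.39 in the authors' deposited table (adjusted p = 3.5e-06), and Mlc1 had -0.39 without passing the test (adjusted p = 0.0521). Among neural progenitor markers, 1 of 11 tested members were higher and 1 lower, or 1 and 2 adjusted over the list alone (median log2 fold change -0.085, camera adjusted p = 0.877). The called members were Btg2, higher, and Hopx, at -0.41 in the authors' deposited table (adjusted p = 0.000682), while Fabp7 had -0.43 (adjusted p = 0.0597).

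Markers of vascular and meningeal cells did not move as a set, although Tagln and Acta2 are members. On that list, 2 of 12 tested members were higher and 0 lower, or 2 and 1 adjusted over the list alone (median log2 fold change 0.048, camera adjusted p = 0.43). The matrix genes Dcn and Col3a1 of the list had -0.27 and -0.23 in the authors' deposited table and did not pass (adjusted p = 0.0824 and 0.306). The astrocyte median lay below the vascular one by more than chance assignment of members gave (difference -0.34, two-sided permutation test p = 0.00582, n = 18 and 12 genes). For the oligodendrocyte lineage, 1 of 7 tested members were higher and 1 lower, or 1 and 1 adjusted over the list alone (median log2 fold change -0.088, camera adjusted p = 0.673), with a mean of 0.021 on the opposite side of 0. Olig2 had -0.41 and Gm98, an older symbol of Myrf, 0.93 in the authors' deposited table (adjusted p = 0.0195 and 0.0293). Only 1 of the microglia markers, Hexb, had an adjusted p, so that list was not tested; its value was 0.30 (adjusted p = 0.00414) in the authors' deposited table.

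Immediate early genes, which neurons transcribe within minutes of activity, were higher in knockdown. On this list 8 of 28 tested members were higher and 1 lower, or 11 and 1 adjusted over the list alone, and 25 had a positive fold change (median log2 fold change 0.24, camera adjusted p = 1.31e-08). Beside Btg2 and Nptx2, the transcription factor genes Atf3 and Jun had 1.04 and 0.27 in the authors' deposited table (adjusted p = 6.27e-06 and 0.000116). Genes of the p53 and DNA damage response were also higher: 6 of 24 tested members were higher and 2 lower, or 9 and 2 adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.00195). Cdkn1a, the p21 cell cycle inhibitor gene, had 0.28, Sesn2 0.26 and Zmat3 -0.27 in the authors' deposited table (adjusted p = 4.18e-05, 0.000655 and 7.23e-07), and Btg2 belongs to this list too. For extracellular matrix genes, 8 of 31 tested members were higher and 4 lower, or 10 and 4 adjusted over the list alone (median log2 fold change 0.084, camera adjusted p = 0.0248). Lamc1, Col6a1 and Col25a1 had 0.50, 0.45 and 0.46 in the authors' deposited table (adjusted p = 8.31e-08, 2.31e-05 and 1.23e-06). The matrix call was lost with a preset correlation of 0.05 between genes (adjusted p = 0.161) and on ranks (adjusted p = 0.219). In the unfolded protein and integrated stress list, 3 of 22 tested members were higher and 3 lower, or 3 and 3 adjusted over the list alone (median log2 fold change 0.058, camera adjusted p = 0.0953). There Chac1 had 0.47 and the chaperone gene Pdia4 -0.52 in the authors' deposited table (adjusted p = 0.00277 and 0.00147).

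Several groups of synaptic and chromatin genes were slightly lower in knockdown, by medians far smaller than those of cell division genes. Of the long neuronal genes fixed as a list, 3 of 66 tested members were higher and 10 lower, or 4 and 13 adjusted over the list alone (median log2 fold change -0.056, camera adjusted p = 0.0031). Grm5, a metabotropic glutamate receptor gene, Unc5d, a netrin receptor gene, Ank2 and Ntm had -0.23, -0.26, -0.22 and -0.21 in the authors' deposited table (adjusted p = 2.42e-05, 3.64e-05, 8.81e-05 and 0.000143). For glutamate receptors and the postsynaptic density, 1 of 38 tested members were higher and 6 lower, or 2 and 9 adjusted over the list alone (median log2 fold change -0.069, camera adjusted p = 0.00768). The AMPA receptor gene Gria1 and the kinase gene Camk2b had -0.24 and -0.26, against 0.19 for the kainate receptor gene Grik3, in the authors' deposited table (adjusted p = 0.000137, 0.000307 and 0.000866). For GABA and glycine receptors, 0 of 19 tested members were higher and 3 lower, or 0 and 4 adjusted over the list alone (median log2 fold change -0.065, camera adjusted p = 0.0112), with Gabrb3 at -0.16 and Gabbr1 at -0.21 in the authors' deposited table (adjusted p = 0.00091 and 0.00407). Readers and writers of DNA methylation and their corepressors were lower too: 0 of 24 tested members were higher and 3 lower, or 0 and 8 adjusted over the list alone (median log2 fold change -0.070, camera adjusted p = 0.0031). Tbl1x, Atrx and Ncor1 had -0.26, -0.24 and -0.16 in the authors' deposited table (adjusted p = 2.04e-06, 2.56e-06 and 0.00275). These 4 calls were lost with a preset correlation of 0.05 (adjusted p = 0.114, 0.114, 0.0878 and 0.0505).

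TOP2B's own transcript was slightly lower in knockdown. Top2b, on chromosome 14, 17197692 to 17263301, had -0.20 in the authors' deposited table (adjusted p = 0.0002). Of the topoisomerase and end repair list, 0 of 18 tested members were higher and 3 lower, or 0 and 3 adjusted over the list alone (median log2 fold change -0.051, camera adjusted p = 0.0953, and 0.0309 over all genes with a p), the called members being Top2b, Atm at -0.21 (adjusted p = 0.021 in the authors' deposited table) and Top2a, which is also a proliferation gene. Of autism genes whose transcription depends on topoisomerases, 0 of 28 tested members were higher and 6 lower, or 0 and 7 adjusted over the list alone (median log2 fold change -0.027, camera adjusted p = 0.0245). Cntnap5a had -0.41 and Unc80 -0.18 in the authors' deposited table (adjusted p = 4.36e-09 and 0.0148), and the call was lost with a correlation of 0.05 (adjusted p = 0.153) and on ranks (adjusted p = 0.13). For ribosomal proteins, 0 of 35 tested members were higher and 2 lower, or 0 and 6 adjusted over the list alone (median log2 fold change -0.080, camera adjusted p = 0.00189), with Rpl19 at -0.18 and Rpl7 at -0.14 in the authors' deposited table (adjusted p = 0.0195 and 0.0329). Only genes over 3 kb are listed and 35 of 55 ribosomal genes were tested. Reads of their pseudogenes can make single values uncertain, which was not tested. For cholesterol synthesis, 0 of 21 tested members were higher and 2 lower, or 0 and 3 adjusted over the list alone (median log2 fold change -0.067, camera adjusted p = 0.0457), with Nsdhl at -0.26 and Srebf2 at -0.17 in the authors' deposited table (adjusted p = 0.0175 and 0.0478). Both calls were lost with a correlation of 0.05 (adjusted p = 0.0505 and 0.167).

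Neuronal identity lists did not move as sets by camera. Glutamatergic markers had 3 higher and 2 lower of 17 (3 and 7 adjusted over the list alone, median -0.037, adjusted p = 0.707). Within them the deep-layer factors Bcl11b, Fezf2 and Tbr1 had 0.21, 0.22 and 0.26 in the authors' deposited table, and Neurod1 had -0.32 (adjusted p = 0.00414, 0.00453, 0.00453 and 0.0247). GABAergic markers had 1 higher and 2 lower of 18 (1 and 2 adjusted over the list alone, median -0.058, adjusted p = 0.162), with Calb1 at -0.30 and Calb2 at 0.24 in the authors' deposited table (adjusted p = 0.00199 and 0.0181). Pan-neuronal genes had 3 higher and 1 lower of 17 (3 and 1 adjusted over the list alone, median 0.0080, adjusted p = 0.673), where the neurofilament gene Nefm had 0.32 and Stmn2 -0.22 in the authors' deposited table (adjusted p = 1.56e-05 and 0.000256). Presynaptic release genes had 3 higher and 2 lower of 30 (3 and 4 adjusted over the list alone, median -0.0040, adjusted p = 0.877), with Stxbp1 at -0.28 and Cplx1 at 0.14 in the authors' deposited table (adjusted p = 0.000207 and 0.0192). Neuropeptides had 0 higher and 0 lower of 17 (0 and 0 adjusted over the list alone, median -0.036, adjusted p = 0.673).

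Ion channel, adhesion and guidance lists held called genes in both directions or few called genes. Potassium channels had 0 higher and 5 lower of 44 (0 and 6 adjusted over the list alone, median -0.032, adjusted p = 0.0937), and passed over all genes with a p (adjusted p = 0.0231), led by Kcnd3 at -0.32 and the glial channel gene Kcnj10 at -0.53 in the authors' deposited table (adjusted p = 5.2e-05 and 0.00316). Sodium and calcium channels had 2 higher and 4 lower of 32 (2 and 4 adjusted over the list alone, median -0.010, adjusted p = 0.673), with Cacnb3 at -0.31 and Scn9a at 0.60 in the authors' deposited table (adjusted p = 0.00132 and 0.0111). Cadherins and protocadherins had 4 higher and 3 lower of 30 (5 and 4 adjusted over the list alone, median -0.0065, adjusted p = 0.673), where Pcdh19 had -0.32 and Pcdh17 0.28 in the authors' deposited table (adjusted p = 2.91e-07 and 3.76e-07). Axon guidance genes had 5 higher and 6 lower of 42 (5 and 8 adjusted over the list alone, median -0.023, adjusted p = 0.502), with Sema6a at -0.24 and Epha4 at -0.26 in the authors' deposited table (adjusted p = 0.000132 and 0.000634). Interferon response genes had 2 higher and 0 lower of 14 (2 and 0 adjusted over the list alone, median -0.0037, adjusted p = 0.678), with B2m at 0.31 in the authors' deposited table (adjusted p = 0.00327). Oxidative phosphorylation genes had 0 higher and 0 lower of 44 (0 and 0 adjusted over the list alone, median 0.0060, adjusted p = 0.673). Genes reported to follow MeCP2 dose had 2 higher and 1 lower of 15 (2 and 1 adjusted over the list alone, median -0.0077, adjusted p = 0.877). Of these, Mef2c was lower at -0.48 and Sgk1 and Igfbp3 higher at 0.23 and 0.35 in the authors' deposited table (adjusted p = 2.65e-13, 0.0132 and 0.0442). The mean or the camera direction was positive against a negative median for the interferon, presynaptic, cadherin and MeCP2 dose lists. In all, camera called 12 of 29 lists with a preset correlation of 0.01, and 4 of them (proliferation, immediate early, astrocyte and p53 genes, the last at adjusted p = 0.0484) with 0.05. An estimated correlation needs values per library, so none was computed.

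**Figure D2:**
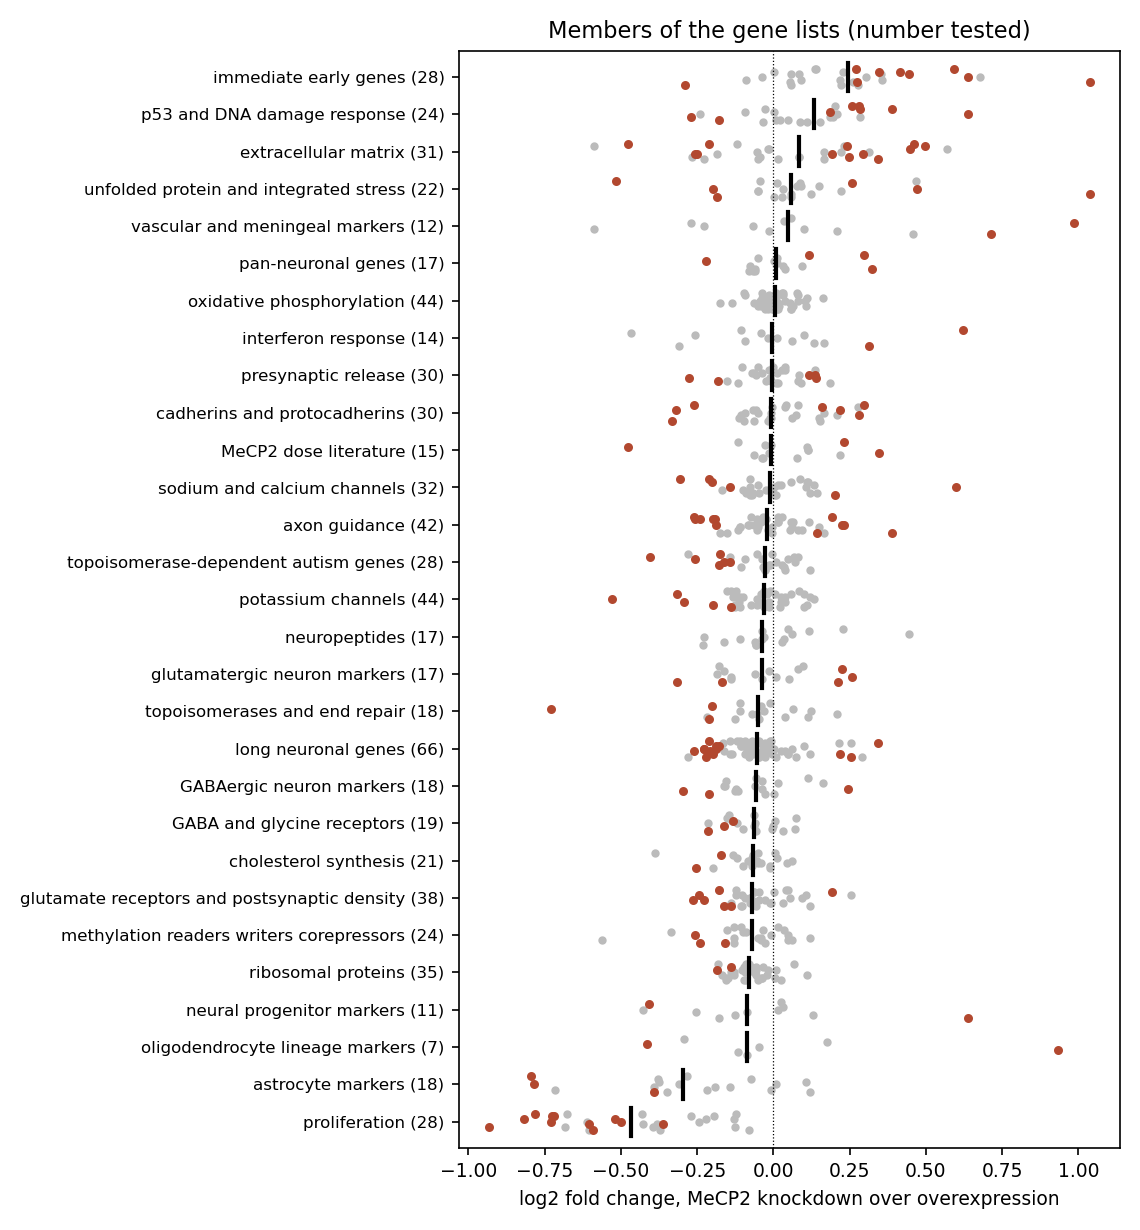
Each point is a tested member of a gene list (rows, number of tested members in parentheses), placed by its log2 fold change in MeCP2 knockdown over overexpression (x axis) from the authors' deposited table. Red points passed an adjusted p of 0.05, grey points did not, vertical black bars are list medians, and the vertical offset of points carries no value. Proliferation genes have the lowest median, -0.47, and immediate early genes the highest, 0.24.

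By camera, transcripts of genes over 100 kb did not shift as a set between knockdown and overexpression. The 2262 tested genes spanning over 100 kb had a median log2 fold change of -0.010, against -0.0024 for the other 11067 (camera adjusted p = 0.769). Long genes were called more often in both directions, however. Of long genes, 134 (5.92%) were higher in knockdown against 3.80% of the others (Fisher's exact test, two-sided p = 1.05e-05). Likewise 182 (8.05%) were lower against 5.20% (Fisher's exact p = 3.29e-07). These tests treat genes as independent, and a difference in read depth between long and other genes could not be corrected for. Above 500 kb, 9 of 195 genes were higher and 28 lower, a lower share of 75.7% of called genes against 57.7% of all called genes (Fisher's exact p = 0.0277 against called genes up to 500 kb, a length limit chosen after the values were seen). The median log2 fold change of these 195 genes was -0.047 (quartiles -0.12 and 0.046), against medians from -0.0062 to 0.00086 in the shorter bins. The 5 longest called genes went both ways. The phosphodiesterase gene Pde4d, the longest at 1506.0 kb on chromosome 13, had 0.19, Cntn4 0.24 and Sdk1 0.24 in the authors' deposited table (adjusted p = 0.0187, 0.0366 and 0.0251). Lingo2 had -0.19 and the neuregulin receptor gene Erbb4 -0.21 in the authors' deposited table (adjusted p = 0.0265 and 0.00246).

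Genes that the table classes as MeCP2-repressed or MeCP2-activated in brain moved, in part, in the direction of their class. How those classes were made is not given in the sources used here. Of 406 tested brain-repressed genes, 66 (16.3%) were higher in knockdown against 4.12% of other classed genes (Fisher's exact p = 9.94e-20), where 19.1 were expected by chance. Another 23 (5.67%) were lower, against 6.02% (Fisher's exact p = 0.915). Among 459 brain-activated genes, 52 (11.3%) were lower against 5.70% (Fisher's exact p = 6.77e-06) and 14 higher against 384 of 8015 others (Fisher's exact p = 0.0891). Collagen and laminin genes were among the brain-repressed genes higher in knockdown: Col4a1 had 0.25 in the authors' deposited table (adjusted p = 0.000184), beside Lamc1, Col6a1 and Col25a1. Lcat, Ptn and Kcnj10 were brain-activated genes lower in knockdown in the authors' deposited table. Exceptions went the other way, such as Mef2c, Neurod1 and Unc5d, classed as repressed and lower in knockdown in the authors' deposited table. As sets, the shifts were small: medians of 0.046 and -0.037 (camera adjusted p = 0.00304 and 0.0197, and 0.465 and 0.52 with a correlation of 0.05). The culture classes of the same table follow its own RNA adjusted p under 0.1 in every row and are not independent evidence.

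eTIP log2 fold changes in knockdown over overexpression were higher for long genes than for other genes. At promoters the long-gene median log2 fold change was 0.091 against -0.021 for other genes (camera adjusted p = 5.7e-09). Over gene bodies it was 0.026 against -0.078 (adjusted p = 4.04e-12). Both held with a correlation of 0.05 (p = 0.00581 and 0.00105, n = 2262 long genes). The promoter call was lost once other genes were matched on promoter log2 CPM: the difference fell from 0.11 (95% bootstrap interval 0.10 to 0.12) to 0.031 (0.019 to 0.043; camera p = 0.101, n = 2262 genes each). Matched on gene-body log2 CPM, the gene-body difference fell from 0.10 (0.10 to 0.11) to 0.030 (0.025 to 0.036), still called (camera p = 0.0156, n = 2262 genes each) but not with a correlation of 0.05 (p = 0.263, n = 2262 genes each). That matching was incomplete, since median log2 CPM stayed at 7.53 for long and 5.97 for other genes. Without matching, the median of the other genes was 4.04, so gene-body log2 CPM itself differs with gene length. The smaller difference after matching therefore cannot separate read depth from length. From the shortest to the longest bin, medians went from -0.089 at 3 to 10 kb to 0.12 above 500 kb at promoters, and from -0.10 to 0.037 over gene bodies. Gene-body medians were negative in every bin up to 100 kb, and the median over all tested genes was -0.052. The gene-body contrast thus lay mostly in lower values of shorter genes. How eTIP values were normalized is not given in the sources used here. Brain-repressed genes stood above other genes of like length and expression in this comparison. Their medians were 0.12 at promoters and 0.054 over gene bodies, above all of 10000 random lists matched on span and TPM, whose medians centred on 0.056 and -0.0028. Camera against all other classed genes, without matching, gave adjusted p = 3.49e-10 and 2.3e-17 (0.0151 and 0.000537 with a correlation of 0.05). The random lists were not matched on eTIP log2 CPM, so a depth effect on this difference was not tested. Brain-activated genes had medians of -0.0098 and -0.087 (adjusted p = 0.446 and 0.148). Single genes rarely passed: 0 gene bodies (1655 at an unadjusted p under 0.05, by the authors' test, whose tool is not given in the sources used here) and 6 promoters, all 6 lower in knockdown. These included Ugt1a1 at -1.76 and Sfi1 at -1.39 in the authors' deposited table (adjusted p = 0.000375 and 0.0115), named after their values were seen. The number of eTIP libraries is not given in the sources used here, and a set test over genes cannot separate a length-dependent difference between libraries from one between conditions.

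**Figure D3:**
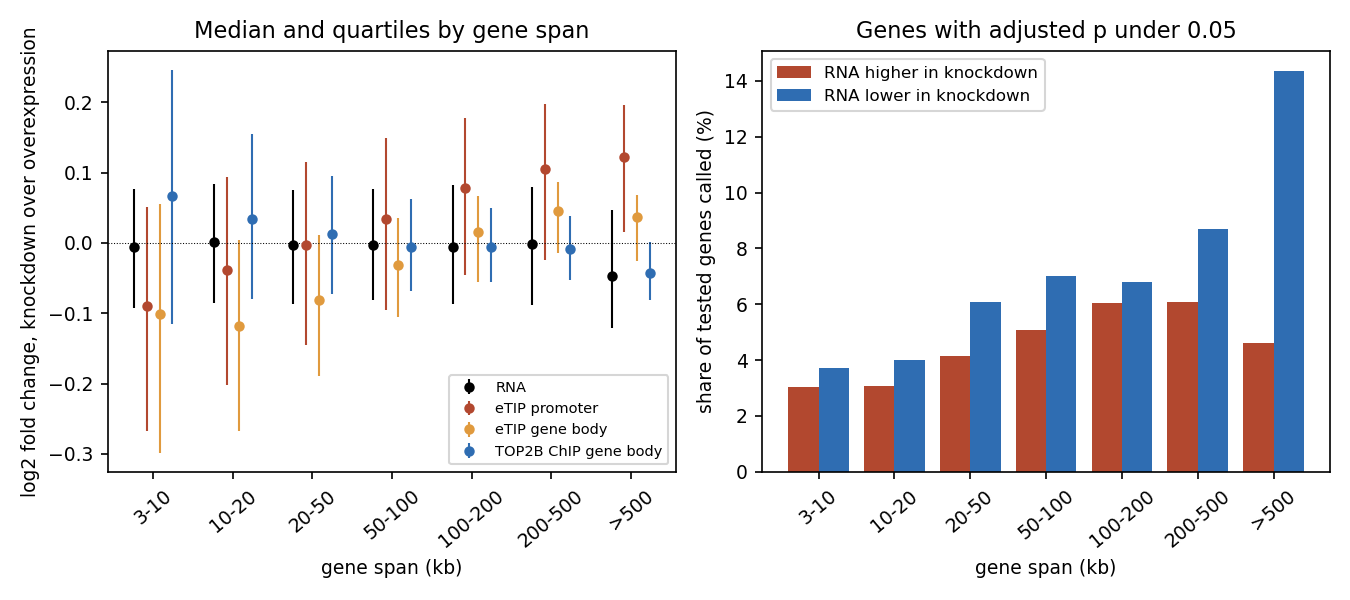
Left, points are median log2 fold changes (y axis) in knockdown over overexpression by gene span in kb (x axis) with bars from the lower to the upper quartile, for RNA, eTIP at promoters and gene bodies, and TOP2B ChIP over gene bodies. Right, bars give the share of tested genes (y axis, %) called higher or lower for RNA; eTIP promoter medians go from -0.089 in the shortest to 0.12 in the longest genes, and called falls from 3.73% to 14.4%.

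At promoters, eTIP was higher in knockdown for genes called in either RNA direction. There, genes higher in knockdown had an eTIP median of 0.060 and genes lower in knockdown 0.050, against about -0.0043 for the others (camera adjusted p = 0.016 and 0.0278). Over gene bodies the medians were 0.00044 and -0.019, where the other genes lay near -0.055 (adjusted p = 0.0031 and 0.0842). With a correlation of 0.05 these calls were lost (adjusted p = 0.52, 0.574 and 0.465). Across the 13329 genes, which are not independent replicates, Spearman's rho between RNA and eTIP fold changes was 0.0329 at promoters and 0.0332 over gene bodies. TOP2B ChIP called 0 genes at promoters and 0 over gene bodies by the authors' test. At an unadjusted p under 0.05 there were 495 and 313 genes, or 2.32% and 1.47%, fewer than that threshold gives by chance. Long genes had a ChIP gene-body median of -0.010 against 0.018 (camera adjusted p = 0.0402, lost with a correlation of 0.05 at p = 0.295), opposite in sign to eTIP. At promoters the ChIP medians were 0.0082 and 0.0062 (adjusted p = 0.975). Genes with higher RNA in knockdown had a ChIP gene-body median of 0.046 against 0.0077 (adjusted p = 0.00467, and 0.465 with a correlation of 0.05).

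Against wild-type cultures, gene-body eTIP log2 fold changes were lower for long genes than for other genes in both manipulations. Short genes rose more than long genes fell: at 3 to 10 kb the gene-body medians were 0.21 with knockdown and 0.33 with overexpression. The gene-body rank correlation with span was -0.442 with knockdown and -0.487 with overexpression. Both comparisons use wild type as the reference, so a trend common to both cannot be tied to the MeCP2 level here. With overexpression, long genes had a gene-body median of -0.037 against 0.16 (camera adjusted p = 3.73e-18) and a promoter median of -0.10 against 0.035 (adjusted p = 7.4e-07). With knockdown, the gene-body medians were -0.017 and 0.072 (adjusted p = 8.38e-08), and the promoter medians -0.024 and 0.0011 (adjusted p = 0.349). Against other genes matched on TPM, the knockdown promoter difference grew from -0.025 to -0.069 and passed (camera p = 0.00408 without adjustment, n = 2262 genes each). Neither comparison with wild type was matched on eTIP log2 CPM, so how far read depth accounts for these long-gene differences was not tested. Brain-repressed genes lay below all 10000 matched lists with overexpression, with medians of -0.15 at promoters and -0.055 over gene bodies (camera adjusted p = 1e-07 and 3.46e-15, and 0.052 and 0.00112 with a correlation of 0.05). With knockdown their medians of -0.033 and -0.0048 lay inside the 95% range of matched lists (adjusted p = 0.211 and 0.00304 against all other classed genes, the latter 0.465 with a correlation of 0.05). The authors called 496 gene bodies with knockdown (407 higher) and 166 with overexpression (145 higher), and 64 and 222 promoters. The insulin-degrading enzyme gene Ide had 0.81 with knockdown and 0.90 with overexpression in the authors' deposited table (adjusted p = 5.33e-10 and 8.48e-10). Skint3 had 3.15 and 4.56 in the authors' deposited table (adjusted p = 7.09e-13 and 4.04e-05), and its wild-type RNA was listed at 0 TPM. Ide and Skint3 were named after their values were seen. In all, 69 gene bodies were higher and 16 lower in both comparisons, which both set wild type as the reference, so an overlap is expected without a shared effect.

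In Mecp2 knockout against wild type, eTIP over genes above 100 kb was not called different from other genes by camera. Gene bodies above 200 kb were lower at an unadjusted p only. The knockout level columns of the table, not used here, are headed in vivo. Long genes had medians of -0.0066 at promoters and -0.020 over gene bodies, against -0.010 and -0.0057 for the others (adjusted p = 0.952 and 0.0918). Above 200 kb the gene-body difference was -0.029 (camera p = 0.00391 without adjustment, n = 920 long genes), and above 100 kb over all genes of the table it was -0.025 (p = 0.0252, n = 2550 long genes). A correlation of 0.05 was not run above 200 kb, and above 100 kb it gave camera p = 0.388 for gene bodies. The median above 500 kb was -0.083. Brain-repressed genes were higher in knockout, with a gene-body median of 0.039 against -0.0092 (camera adjusted p = 0.00304), and brain-activated genes lower at -0.048 (adjusted p = 0.0407). Both calls were lost with a correlation of 0.05 (adjusted p = 0.465 and 0.581), while both medians lay outside all 10000 matched random lists. The authors called 51 gene bodies, 12 of them higher in knockout. Mmp16, a brain-activated metalloproteinase gene, had -0.49, and Sptlc1, a sphingolipid synthesis gene, had 0.39 in the authors' deposited table (adjusted p = 0.000103 and 0.00233), both named after their values were seen.

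**Figure D4:**
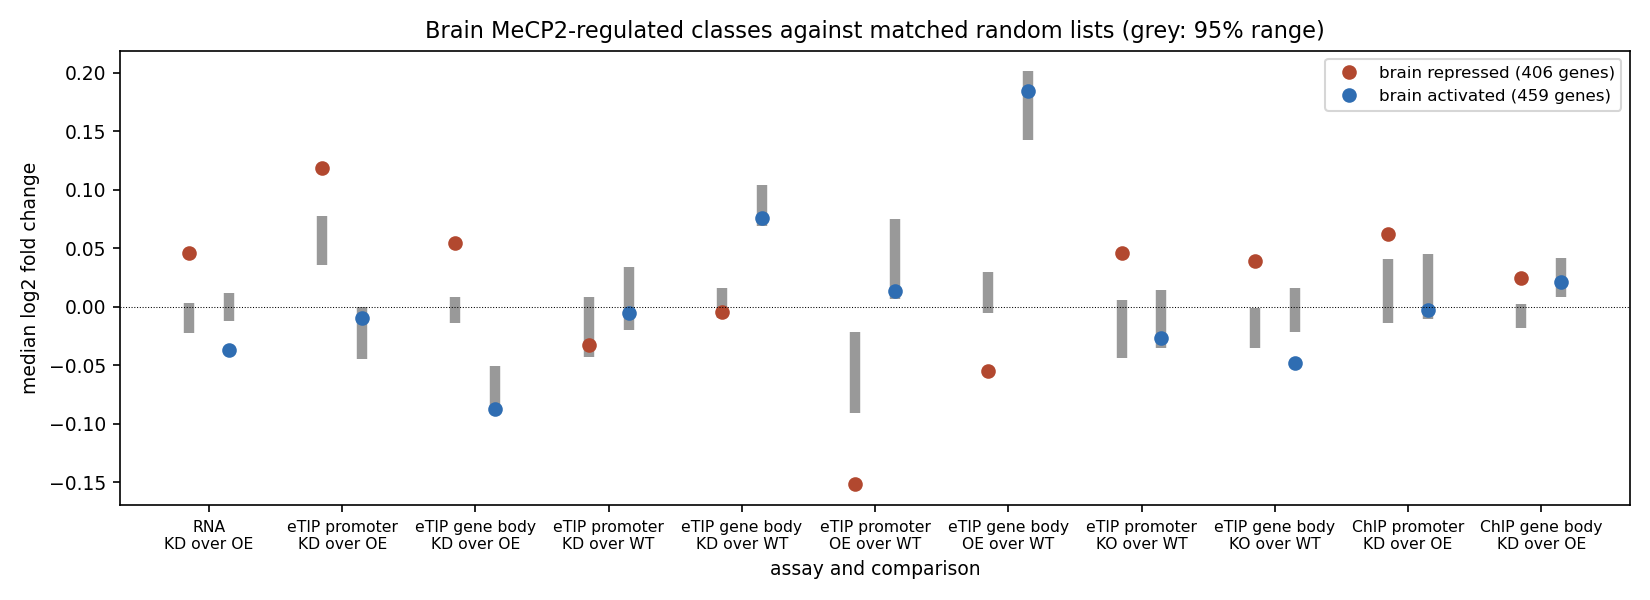
Points are median log2 fold changes (y axis) of genes classed in brain as MeCP2-repressed (red) or MeCP2-activated (blue), by assay and comparison (x axis; KD knockdown, OE overexpression, KO knockout, WT wild type), and grey bars span the 95% range of 10000 random lists matched on gene span and wild-type TPM. Brain-repressed genes lie above the range in KD over OE and KO over WT, for example 0.054 for gene-body eTIP in KD over OE, within it in KD over WT and below it in OE over WT, with -0.055 over gene bodies. Brain-activated genes lie below it for RNA at -0.037 and for gene bodies in KO over WT, and within it elsewhere.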

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

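All genes with a p (for the counts of called genes and long-gene RNA) and the 50 and 200 kb limits (for long-gene RNA) were chosen before the data were seen, and all other alternatives after. Of 210 recomputed values, 174 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 27 fell short of the threshold, 5 newly passed it and 4 reversed. The 5 that passed were promoter eTIP of long genes in knockdown over wild type matched on TPM (-0.069), gene-body eTIP in knockout over wild type above 200 kb (-0.029) and over all genes of the table (-0.025), and, over all genes with a p, topoisomerases and end repair (-0.051, adjusted p = 0.0309) and potassium channels (-0.032, adjusted p = 0.0231). None of the 4 reversed values was called before or after: long genes for promoter eTIP in knockout over wild type (-0.00019 above 50 kb and -0.0050 over all genes of the table, from 0.0037), long genes for promoter ChIP (-0.0066 above 200 kb, from 0.0021) and oligodendrocyte genes (0.021 over all genes with a p, from -0.088). The count of 1312 called genes became 1152 when the adjustment ran over all genes with a p, 1346 over the table's own genes, 1198 with a TPM of at least 1 and 1842 at a threshold of 0.1. Long-gene RNA stayed without a call under every alternative run (p from 0.18 matched on TPM to 0.826 with a correlation of 0.05). The gene-body eTIP call for long genes in knockdown over overexpression passed with each alternative applied alone. Matched, incompletely, on gene-body log2 CPM, the difference was 0.030 instead of 0.10, and a correlation of 0.05 on top of that matching ended the call (camera p = 0.263). That log2 CPM is itself higher in long genes, so the matching cannot separate read depth from length. The promoter call was lost once other genes were matched on promoter log2 CPM (0.031, from 0.11) and kept otherwise. A preset correlation of 0.05, which widens every set test by construction, ended 8 list calls at unchanged medians: methylation readers (-0.070), long neuronal genes (-0.056), topoisomerase-dependent autism genes (-0.027), cholesterol synthesis (-0.067), ribosomal proteins (-0.080), glutamate receptors (-0.069), GABA receptors (-0.065) and extracellular matrix (0.084). On ranks, the autism genes (-0.027) and extracellular matrix (0.084) were also lost, and the cause was not tested. The correlation of 0.05 also ended 15 of the brain-class and called-gene set calls and the ChIP long-gene call.

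No paired analysis was possible because the table holds no column for a single library, although overexpression and knockdown share replicate numbers 1 to 8 in the labels. For the same reason other normalizations, other count tests, fits of 2 groups only, replicates 1 to 4 or 5 to 8, leave-one-out fits, split controls, another feature count, an estimated correlation and permuted splits of the samples were not run. Depth per library is unknown, so whether uncalled genes differ by less than the called median cannot be stated.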

Other observations

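Some single promoters were called in eTIP. The glial potassium channel gene Kcnj10 had a promoter eTIP log2 fold change of 1.15 in knockdown over wild type in the authors' deposited table (adjusted p = 0.000393), while its RNA was lower in knockdown than in overexpression at -0.53 (adjusted p = 0.00316). Ptgfr, a prostaglandin receptor gene, had 0.95 at its promoter in the same comparison of the authors' deposited table (adjusted p = 0.000295). In knockout over wild type, 3 promoters were called, among them Rabif at 1.11 and Mmab, a cobalamin enzyme gene, at 1.15 in the authors' deposited table (adjusted p = 0.0021 and 0.0291). These genes were named after their values were seen.

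The tests of cell shares in knockdown cultures were chosen after the list results were seen, and the other tests before their results were seen.

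Lower division and astrocyte genes in knockdown had the lowest medians of the lists tested. A lower share of all non-neuronal cells in knockdown cultures would lower vascular and meningeal markers too, yet the astrocyte median lay -0.34 from theirs on the log2 scale (permutation test p = 0.00582), and the vascular median was 0.0476. The 2 lists thus did not fall alike. Vascular members were mixed, however, with 7 of 12 positive and 5 negative. The permutation ran over genes and not over cultures, so it does not decide on a loss of non-neuronal cells. Fewer cells of the astrocyte lineage would lower astrocyte markers as a set, but their median of -0.30 is the pattern itself and decides nothing. Fewer such cells with knockdown, more with overexpression and lower expression per astrocyte all stay open, since neither cell counts nor control RNA were analysed here.

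The eTIP gene-body differences from wild type called in both manipulations covered 85 genes. Whether an expression difference at the called genes made them stays open: 37.6% had a TPM of at least 1 (exact binomial 95% interval 27.4% to 48.8%) against 56.4% of all genes, but 69 of the 85 were higher than wild type in eTIP, and genes switched on in both manipulations would also have low wild-type TPM, so that share decides nothing. Called genes lay near each other: 40% had another within 1 Mb, against 18.8% at the 95th percentile of 10000 random sets. Examples are Skint3, Skint9 and Skint6 on chromosome 4 and Hjurp and Heatr7b1 on chromosome 1. The spans of Hjurp and Heatr7b1 overlap, so their values can share reads, while those of the named Skint genes do not overlap. A candidate explanation is a strain or locus copy variant between the wild-type libraries and those of both manipulations. Neighbouring genes that change together, reads shared by overlapping genes, or wild-type libraries shared by both comparisons stay open, and no other biological explanation was tested.

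The promoter eTIP rise with gene length in knockdown over overexpression could reflect the libraries rather than MeCP2. Against wild type, promoter eTIP fell with length in both, with a rank correlation of -0.0808 for knockdown and -0.258 for overexpression, so the rise is a smaller fall in knockdown. If a background or enrichment difference between eTIP libraries made it, genes hardly expressed should show it: their rank correlation with span was 0.087 (95% bootstrap interval 0.0607 to 0.111), under that of expressed genes, 0.297. Their long-minus-other difference, however, was 0.11 against 0.13, nearly as large, so the rank correlation set as the criterion missed this difference and the explanation stays undecided. Over gene bodies, genes hardly expressed had a rank correlation of -0.0221 (95% bootstrap interval -0.0467 to 0.00399) against 0.241, and a long-minus-other difference of 0.062 against 0.12, so there the trend was weaker in them. Low read depth over the promoter region is in line with the drop of the difference from 0.11 to 0.033 once genes were matched in 20 bins of promoter log2 CPM. Matching in pairs, chosen after that result was seen, left 0.031 and ended the camera call. Matching on that signal can also remove a real dependence on TOP2B engagement, so a MeCP2 effect on long genes and a depth effect both stay open.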
